A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

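Ribosome footprints and mRNA fragments were measured in 16 libraries of sporulating SK1 yeast. Per the labels' protocols, cells were treated with 100 µM cycloheximide for 1 min before harvest, footprints of 28 to 31 nt and mRNA fragments of 50 nt were selected, and libraries were made by linker ligation and circularisation. The authors deposited 1 table of RPKM values (reads normalised to gene length and library depth) for 6679 genes, with 1 column per library and no pooling. CASAVA, bcl2fastq 2.17 and Bowtie2 are named per the submitters' processing notes, with no role given. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here, so overlapping and antisense genes, and near-identical copies, may share reads. Columns were matched to samples by the library names in the labels, and none was left over. Gene names came from the table and from RefSeq locus tags of assembly R64, which matched 5994 of 6679 IDs and were used for names and neighbours only.

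Whole reads were recovered from the steps of the RPKM values, within 0.02 of a whole read, for 6678 of 6679 genes in mRNA and for 6679 in footprints. Depth was 5484141 to 8905160 reads per mRNA library and 4570737 to 6953168 per footprint library. At 4 to 6 RPKM a gene had a median of 36.1 reads per mRNA library and 40.9 per footprint library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors on reads cover counting error only. A floor of 3 reads over a group was used where all its libraries were at 0.

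Genes with a mean of at least 5 RPKM over the 8 libraries of a kind were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and understate the change of low genes. Each kind of library was fitted with means of its 4 groups. Translation efficiency was tested in 1 model over all 16 libraries as the footprint change minus the mRNA change. The contrasts were deletion against WT at 3 h, at 6 h and averaged over the times, the difference of that effect between the times, and 6 h against 3 h in WT.

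The 17 gene lists were fixed before the data were examined: DBP1 locus and paralogue (named gene by gene), translation initiation factors, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, TCA and glyoxylate cycles, early and middle meiotic genes, late sporulation and spore wall, heat shock and chaperones, ribosome biogenesis, amino acid biosynthesis, proteasome, autophagy, and markers of dividing cells and of haploid cells. The 16 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Genes were named by a rule fixed at the same time: per comparison and measurement, among genes past the threshold whose groups did not overlap library by library, the 10 with the largest rise and the 10 with the largest fall; where none passed in a direction, the 3 genes of smallest p; always DBP1, DED1, MRP51 and VPS30; and up to 4 members of smallest p of a list described.

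Each library was placed between the WT 3 h mean and the WT 6 h mean by projection, over genes passing the filter in both kinds, with weights from the other kind of library. Pairs of libraries were compared by a chi-square statistic of their recovered reads over genes with at least 20 summed reads. Every pair of replicates differed by more than sampling noise, the mean statistic being at least 3.76 where sampling alone gives about 1, so no library was counted as deposited more than once. Steps were tested on simulated data with 200 changed genes per comparison and noise drawn independently for each gene and library. With fewer changed genes the adjustment is stricter, so a smaller share would be recovered. For footprints averaged over the times, 95 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2 were recovered among 5312 genes, with 2 false calls. Alternatives were a pseudocount of 5 RPKM, no filter on low values, rescaling by the median ratio, limma without the trend, a replicate block, the sample numbers as a covariate and leaving out each replicate. Added after the data were seen were limma-voom on the recovered reads and leaving out the mRNA library labelled deletion 3 h replicate 2, with and without rescaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.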

Results

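Budding yeast of the SK1 background, a strain used for its fast and synchronous sporulation, was sampled 3 h and 6 h after transfer to sporulation medium. Cells either carried the DBP1 open reading frame (WT) or had it removed by a markerless Cas9-based strategy. DBP1 encodes a DEAD-box RNA helicase and is the paralogue of DED1, a helicase of translation initiation. Libraries were made of ribosome footprints, the stretches of mRNA covered by ribosomes, and of mRNA fragments. The 8 groups (2 kinds of library, 2 strains, 2 times) held 2 libraries each, 16 in all. WT replicates were numbered 3 and 4 and deletion replicates 2 and 4. Nothing in the labels said that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The reads assigned to genes, recovered from the steps of the RPKM values, ranged from 5484141 to 8905160 per mRNA library and from 4570737 to 6953168 per footprint library.

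DBP1 was lost from every library labelled as deletion. Its footprint level in WT was 423 ± 9.14 RPKM (SD, n = 2) at 3 h and 155 ± 12.4 RPKM (SD, n = 2) at 6 h, against 1.09 ± 0.0458 RPKM (SD, n = 2) and 0.513 ± 0.0914 RPKM (SD, n = 2) in the deletion. DBP1 mRNA in WT was 159 ± 2.89 RPKM (SD, n = 2) at 3 h and 36.5 ± 5.95 RPKM (SD, n = 2) at 6 h. In the deletion the mRNA libraries labelled 3 h held 1.25 and 0.633 RPKM of DBP1 (20 and 8 reads), and those labelled 6 h held 1.22 and 0.409 RPKM (20 and 6 reads). On the log2 scale footprints fell by 7.67 (SE 0.15, adjusted p = 1.1e-07) at 3 h and by 6.69 (SE 0.15, adjusted p = 3.4e-07) at 6 h. DBP1 mRNA fell by 6.38 (SE 0.41, adjusted p = 0.0061) at 3 h. At 6 h its log2 change of -4.40 (SE 0.41, adjusted p = 0.075) did not pass with all libraries. Without WT replicate 3 or 4 the log2 change of DBP1 mRNA at 3 h was -6.40 and -6.36, and neither passed the threshold. Those fits kept a deletion mRNA library that did not match the time on its label, described below. They thus do not show whether the call rests on a lone WT replicate. Without that deletion library the change at 3 h was -6.61.

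**Figure D1:**
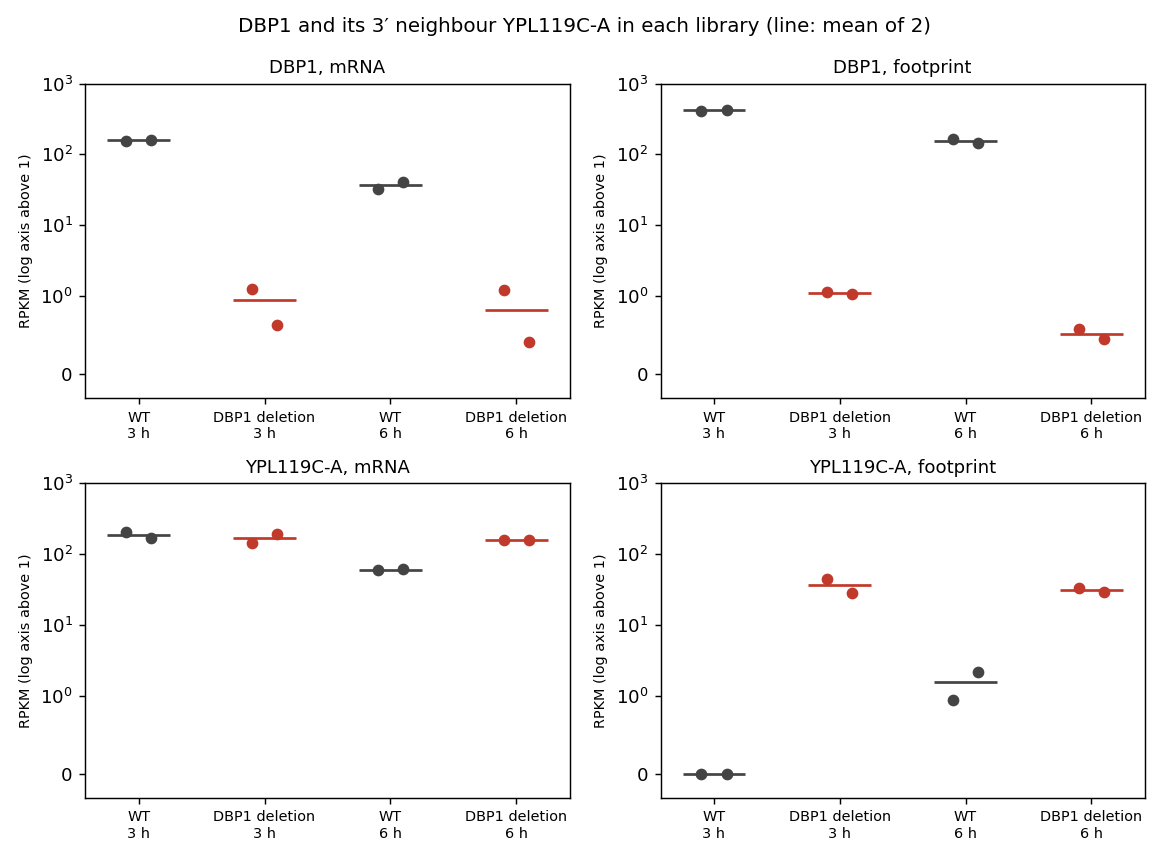
RPKM of DBP1 and of YPL119C-A, the next gene on its 3′ side, in each library (points) with the mean of the 2 libraries of a group (line), on an axis that is linear to 1 and logarithmic above. DBP1 was near 1 RPKM or below in the deletion, while YPL119C-A held 0 footprint reads in both WT libraries at 3 h and 63 and 30 reads in the deletion libraries.

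One library did not match the time on its label. The mRNA library labelled deletion 3 h replicate 2 stood at 0.913 on a scale on which the WT 3 h profile is 0 and the WT 6 h profile is 1. The other deletion mRNA library labelled 3 h stood at 0.0608, and the deletion mRNA libraries labelled 6 h at 0.926 and 1.03. The footprint library of the same strain, time, replicate and sample number stood at 0.0164. Across genes, the log2 values of the library correlated at 0.993 with the deletion 6 h replicate 2 mRNA library and at 0.693 with the other library of its own group (genes are not independent replicates). CCW22, a cell wall protein gene chosen after its values were seen, stood at 87042 RPKM in it, against 3787 ± 388 RPKM (SD, n = 2) in WT at 3 h. Because of this library, mRNA and translation efficiency were tested with it and also without it, which was chosen after the data were seen.

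**Figure D2:**
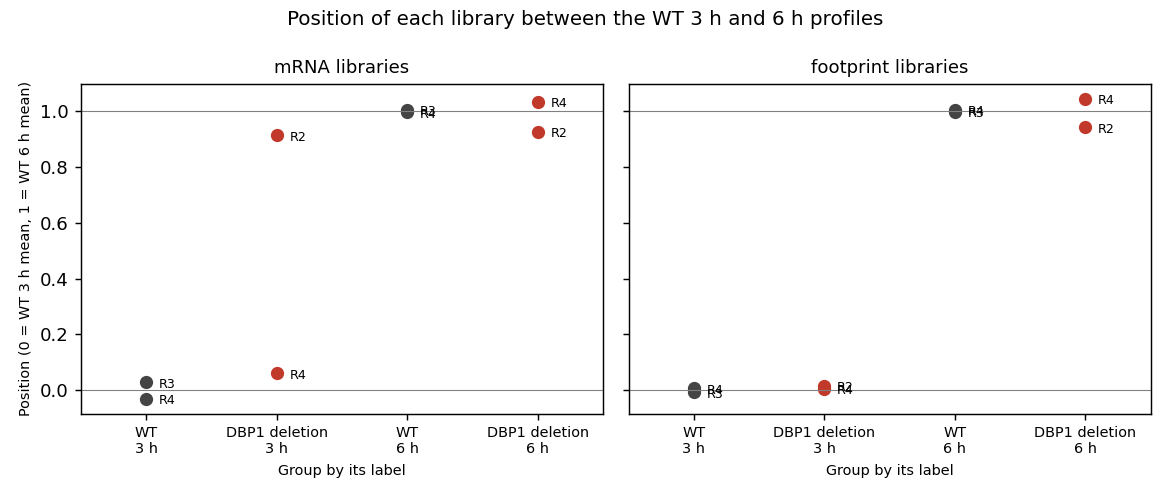
Position of each of the 16 libraries between the WT 3 h mean (0) and the WT 6 h mean (1), by the group on its label, mRNA on the left and footprints on the right. The mRNA library labelled deletion 3 h replicate 2 lies at 0.913, and the footprint library of that strain, time and replicate at 0.0164.

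The footprint comparison asked which genes changed in ribosome occupancy without DBP1. Beside DBP1 itself, footprints rose in YPL119C-A, a short open reading frame of unknown function that is the next gene on the 3′ side of DBP1, on the same strand. Its WT libraries held 0 reads at 3 h and 1 and 2 reads at 6 h, and the deletion libraries held 63 and 30 reads at 3 h and 39 and 29 at 6 h. At 3 h footprints in the deletion were at least 27.2-fold higher, taking the floor of 3 reads over the 2 WT libraries. At 6 h they were 20.9-fold higher (95% exact binomial interval 6.85 to 104, counting error only). The fitted log2 change of RPKM + 1 was 5.20 (SE 0.31, adjusted p = 4.3e-04) at 3 h, 3.70 (SE 0.31, adjusted p = 0.0059) at 6 h and 4.45 (SE 0.22, adjusted p = 9.7e-05) averaged over the times. The third called gene, YBL039C-A, fell by 3.24 (SE 0.32, adjusted p = 0.016) at 6 h but held at most 3 reads in any footprint library. At 6 h neither YPL119C-A nor YBL039C-A was called by limma-voom on the recovered reads (adjusted p = 0.199 and adjusted p = 0.999), which called DBP1 alone. Without deletion replicate 2 the adjusted p of YPL119C-A at 6 h was 0.0946, and without WT replicate 3 it was 0.119. That of YBL039C-A was 0.0579 without deletion replicate 2, 0.308 without WT replicate 3 and 0.427 without WT replicate 4.

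Of 5312 genes, limma called 1 higher and 1 lower in the deletion at 3 h, 1 higher and 2 lower at 6 h, and 1 higher and 1 lower averaged over the times. Without deletion replicate 4 these counts were 77, 11 and 123, and without deletion replicate 2 or without WT replicate 3 the count at 6 h was 1. DED1 footprints were 544 ± 37.8 RPKM (SD, n = 2) in the deletion and 421 ± 35.3 RPKM (SD, n = 2) in WT at 3 h, a log2 change averaged over the times of 0.40 (SE 0.14, adjusted p = 1.00) that did not pass the threshold. The flanking genes MRP51, for a mitochondrial ribosomal protein, and VPS30, for a subunit of a phosphatidylinositol 3-kinase complex, had average log2 changes of -0.27 (SE 0.13) and -0.16 (SE 0.11), both with an adjusted p of 1.00. The 95% interval of the average change lay within 1 on the log2 scale for 96.4% of genes. In data simulated with the spread of this comparison, 95% of genes changed by 1 on the log2 scale and 99% of those changed by 2 were recovered among 5312 genes. Those data held 200 changed genes, and with fewer the adjustment would be stricter and recovery lower. Their noise was independent per gene and library, with no replicate standing apart as deletion replicate 2 did. For the difference of the effect of the deletion between 6 h and 3 h, limma called 0 genes, with 78 genes at an unadjusted p under 0.05 and 0 genes by limma-voom. It called 1 gene without WT replicate 3 and 1 with libraries rescaled by the median ratio. In simulated data for this comparison, 44% of genes changed by 1 and 93% of those changed by 2 were recovered among 5312 genes. YBL039C-A came closest, at -4.25 (SE 0.46, adjusted p = 0.081), and DBP1 had 0.97 (SE 0.21) and YPL119C-A -1.50 (SE 0.44, 95% interval -2.51 to -0.48, adjusted p = 1.00). DMO2 and DIT1, for an enzyme of spore wall dityrosine, had differences of 0.66 (SE 0.18) and 2.10 (SE 0.65), and YOL014W and HXT14, for a hexose transporter, of -1.02 (SE 0.20) and -0.67 (SE 0.16), all with an adjusted p of 1.00.

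**Figure D3:**
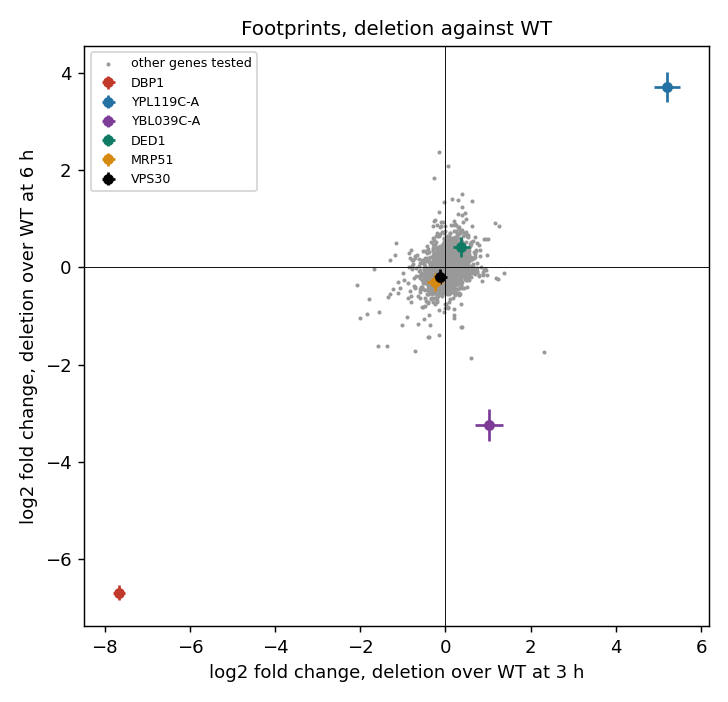
Footprint log2 fold change of RPKM + 1, deletion over WT, at 3 h (horizontal) and 6 h (vertical) for each of the 5312 genes tested, with bars of 1 SE for the named genes. DBP1 lies at -7.67 and -6.69 and YPL119C-A at 5.20 and 3.70, and YBL039C-A at 6 h rests on at most 3 reads per library.

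None of the lists tested in footprints had a member past the all-gene threshold between the strains. Not tested there were the list of DBP1, its paralogue and its neighbours, and the mitochondrially encoded list, which was tested in mRNA alone. With the preset correlation of camera, middle meiotic genes stood above other genes in the deletion at 3 h: 39 of 46 were higher, with a median log2 change of 0.25 (adjusted p = 2.6e-16), and 4 passed adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.144). Its members of smallest p were SPR3, a septin of the sporulating cell (0.66, SE 0.13), OSW1 (0.66, SE 0.14), SPO77 (0.88, SE 0.20) and SPS22 (0.52, SE 0.12). The late sporulation and spore wall list had a median of 0.19 at 3 h (adjusted p = 4.3e-04 preset, adjusted p = 0.144 with an estimated correlation) over 12 genes, with 4 past the threshold adjusted over the list alone, among them LDS2 (0.69, SE 0.13) and LDS1 (0.62, SE 0.14). In mRNA at 3 h, deletion replicate 4 had 45 of 46 middle meiotic genes above WT, with a median log2 difference of 0.87. Its late sporulation median was 0.72. The other mRNA library of that group did not match its label. The footprint shifts of these 2 lists thus do not show a change in footprints per mRNA. Averaged over the times, 76 of 82 ribosome biogenesis genes were higher, with a median of 0.23 (adjusted p = 7.3e-13 preset, adjusted p = 0.668 with an estimated correlation). At 6 h their median difference from WT was 0.53 in deletion replicate 2, whose footprint libraries stood apart from the others, and -0.12 in replicate 4. Of 75 mitochondrial ribosomal protein genes 6 were higher, with a median of -0.11 (adjusted p = 1.1e-07 preset, adjusted p = 0.712 with an estimated correlation). Their medians were -0.24 at 3 h and -0.31 at 6 h in replicate 2, and 0.05 and 0.00 in replicate 4, where 53 and 39 genes were above WT. Among 25 translation initiation factors, none passed adjusted over the list alone. No list call between the strains held with an estimated correlation.

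For mRNA, limma called DBP1 alone at 3 h and averaged over the times (5712 genes tested), with and without the library that did not match its label. At 6 h it called 0 genes with all libraries (5 at an unadjusted p under 0.05, 0 by limma-voom) and 2 without that library. The 2 genes were DBP1, with a log2 change of -4.40 (SE 0.24), and YPL119C-A, which was 60.1 ± 0.777 RPKM (SD, n = 2) in WT and 160 ± 0.876 RPKM (SD, n = 2) in the deletion (log2 change 1.40, SE 0.12, adjusted p = 0.028). At 3 h YPL119C-A mRNA changed by 0.05 (SE 0.15, adjusted p = 1.00) without that library. MRP51 mRNA was 109 ± 0.695 RPKM (SD, n = 2) in WT at 3 h, and its average log2 change was 0.01 (SE 0.10) without that library; those of DED1 and VPS30 were -0.03 (SE 0.11) and -0.01 (SE 0.11). Without deletion replicate 4, which leaves that library alone in its group, 5069, 53 and 4641 genes were called at 3 h, at 6 h and averaged, and without WT replicate 3 or 4 there were 0 (at most 64 at an unadjusted p under 0.05). The fits without a WT replicate kept the library that did not match its label. At 3 h YJR087W, PAU10 and YOR011W-A had the smallest p among higher genes, with log2 changes of 2.75 (SE 0.79), 2.89 (SE 0.84) and 3.87 (SE 1.17) that did not pass (adjusted p = 0.404). Without that library, which leaves a lone deletion library at 3 h, their changes were 1.55, 1.50 and 2.11. At 6 h the genes after YPL119C-A and DBP1 were YGL193C (1.50, SE 0.62), COX17, for a copper chaperone of cytochrome c oxidase (1.76, SE 0.78), YMR315W-A (-2.11, SE 0.86, at most 5 reads per library) and YGR174W-A (-1.91, SE 0.78), all with an adjusted p of 1.00. Averaged over the times they were YIL156W-A (0.76, SE 0.30) and YLR012C (2.52, SE 1.02), with an adjusted p of 0.694. Without the library that did not match its label these changes were 0.71 and 1.37. The library that did not match its label widened the median 95% interval of the average change from ± 0.29 to ± 0.84. In data simulated with the spread without it, 87% of genes changed by 1 on the log2 scale were recovered, against 6% with it, among 5712 genes. For a difference of the effect between the times limma called 0 genes with all libraries (15 at an unadjusted p under 0.05, 0 by limma-voom) and 0 without that library (239 at an unadjusted p under 0.05), against 4866 without deletion replicate 4. Of simulated differences of 2 on the log2 scale, 0% were recovered with that library and 80% without it. DAD3, for a kinetochore protein, had a difference of -1.38 (SE 0.52), YJR087W of -3.34 (SE 1.12) and PAU10 of -3.18 (SE 1.19), and YPL119C-A, DBP1 and YHL048C-A had 1.55 (SE 0.41), 1.98 (SE 0.58) and 1.84 (SE 0.61), all with an adjusted p of 0.651. Without that library the differences, in the same order, were -0.90, -2.14, -1.79, 1.35, 2.21 and 1.44.

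Translation efficiency, footprint over mRNA, was tested in 1 model over both kinds of library. YPL119C-A rose at 3 h (log2 change 5.35, SE 0.41, adjusted p = 2.0e-04) and averaged over the times (3.83, SE 0.29), and no other gene of 5290 was called with all libraries. The WT footprint libraries held 0 reads of YPL119C-A at 3 h and 1 and 2 reads at 6 h, so the size of its changes depends on the pseudocount. Both calls of YPL119C-A were lost when efficiency was taken as footprint minus mRNA per sample number. Without the library that did not match its label, the changes were 5.15 (SE 0.38) at 3 h and 3.73 (SE 0.26) averaged, and DBP1 was the other gene called, at 6 h (-2.30, SE 0.28) and averaged (-1.68, SE 0.21). As its reading frame was removed, its values in the deletion are 4 to 20 residual reads per library near the pseudocount and measure no efficiency. With all libraries but without WT replicate 3 or 4, the changes of YPL119C-A at 3 h were 5.22 (adjusted p = 0.303) and 5.48 (adjusted p = 0.217), and 0 genes were called (7 and 4 at an unadjusted p under 0.05). Averaged over the times its changes were then 3.60 (adjusted p = 0.365) and 4.06 (adjusted p = 0.156). Without deletion replicate 4, 4436 genes were called at 3 h, 1 at 6 h and 3807 averaged. At 6 h 0 genes passed with all libraries (5 at an unadjusted p under 0.05, 0 by limma-voom), YPL119C-A having a change of 2.31 (SE 0.41, adjusted p = 0.383). NRG2, MIN9 (1.32, SE 0.68), YNL146C-A (-2.77, SE 0.78) and YBL039C-A (-5.78, SE 1.48) came next at 6 h, all with an adjusted p of 1.00. At 3 h YOR011W-A and EFG1 had the smallest p among lower genes, with changes of -5.54 (SE 1.41) and -2.78 (SE 0.74) and an adjusted p of 0.445. That fit set the 3 h footprints partly against the mRNA library that did not match its label. An effect of the deletion on these genes cannot be told apart from that. The same limit holds for the values with all libraries given below. DED1, MRP51 and VPS30 had average efficiency changes of 0.43 (SE 0.19), -0.28 (SE 0.18) and -0.14 (SE 0.15) without that library, none past the threshold. For a difference of the effect on efficiency between the times limma called 0 genes (11 at an unadjusted p under 0.05, 0 by limma-voom), and 0 without that library (54 at an unadjusted p under 0.05), against 4036 without deletion replicate 4. Of simulated differences of 2 among 5290 genes, 0% were recovered with that library and 74% without it. YPL119C-A had the smallest p, with a difference of -3.05 (SE 0.58), followed among lower genes by YNL146C-A (-3.67, SE 1.10) and YLR146W-A (-4.08, SE 1.65), and the higher genes of smallest p were YOR011W-A (5.62, SE 2.00), DAD3 (1.27, SE 0.56) and EFG1 (2.37, SE 1.05), all with an adjusted p of 0.702. Averaged over the times YBL039C-A (-3.42, SE 1.05) and EFG1 (-1.60, SE 0.53) came after DBP1 among lower genes, with an adjusted p of 0.750.

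The comparison of 6 h with 3 h in WT gives the course of sporulation. Footprints of 1068 genes rose and of 3362 fell among 5312 tested. The median log2 change of all genes was -0.96 in RPKM, which is relative within a library, and with libraries rescaled by the median ratio the split was 1920 higher and 1707 lower. The steepest rises were of SPR2, a spore wall protein gene (8.77, SE 0.24), SPS2 (8.67, SE 0.19), SPO19 (8.61, SE 0.22), RRT12 (8.61, SE 0.21), ISC10 (8.58, SE 0.35), GIP1, a meiotic subunit of protein phosphatase 1 (8.57, SE 0.14), SPS1, a sporulation kinase (8.54, SE 0.26), GAT4 (8.49, SE 0.32), RRT5 (8.48, SE 0.21) and SRD1 (8.45, SE 0.28). The steepest falls were of SCW10 (-4.06, SE 0.51), URA1 (-3.81, SE 0.40), PRY2 (-3.62, SE 0.35), YOL038C-A (-3.59, SE 0.78, at most 9 reads per library), JEN1, a lactate transporter (-3.57, SE 0.14), CTR3, a copper transporter (-3.52, SE 1.30), NCW2 (-3.42, SE 0.47), CPA1 (-3.30, SE 0.47), SIM1 (-3.25, SE 0.33) and PIR1 (-3.24, SE 0.73). DBP1 footprints fell by 1.44 (SE 0.15) and those of DED1 by 2.07 (SE 0.20). CTR3 was not called with rescaled libraries.

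Footprints of 45 of 46 middle meiotic genes rose, with a median of 6.86 (adjusted p = 3.1e-37 preset, adjusted p = 0.0331 with an estimated correlation), including SPS22, PES4, GIP1 and SPR3. Of 12 late sporulation and spore wall genes, 10 rose and 1 fell (median 5.69, adjusted p = 0.0331 with an estimated correlation), LOH1 by 8.01 (SE 0.13). Of 38 early meiotic genes, which serve recombination and chromosome pairing, 37 fell (median -1.74), among them DMC1, the meiotic recombinase (-2.18, SE 0.18), and MEI5 (-1.94, SE 0.15). All 36 oxidative phosphorylation genes fell (median -2.10), ATP1 by 2.80 (SE 0.16). Relative to other genes the medians of these lists were -0.79 and -1.15, and with rescaled libraries 31 early meiotic genes fell and 1 rose, and 27 oxidative phosphorylation genes fell. The preset test called both lists (adjusted p = 4.7e-04 and adjusted p = 2.7e-05), and the calls were lost with an estimated correlation (adjusted p = 0.830 and adjusted p = 0.808). Of 134 cytosolic ribosomal protein genes 111 fell and 2 rose (median -1.31; 112 and 2 adjusted over the list alone), of 33 proteasome genes 32 fell (median -1.01) and of 82 ribosome biogenesis genes 62 fell and 7 rose, DBP3 by 3.98 (SE 0.14). With rescaled libraries 34 of the ribosomal protein genes fell and 14 rose, 2 of the proteasome genes fell and 4 rose, and 39 of the ribosome biogenesis genes fell and 13 rose. The preset test called the ribosomal protein and proteasome lists (adjusted p = 0.0069 and adjusted p = 0.0103), and both calls were lost (adjusted p = 0.830 with an estimated correlation).

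The remaining lists moved in both directions, and adjusted over the list alone their counts were the same. With rescaled libraries more members rose than fell in the mitochondrial ribosomal protein (35 and 13), heat shock (12 and 5), autophagy (12 and 5), amino acid biosynthesis (19 and 17), dividing cell (9 and 8) and haploid-specific (8 and 1) lists. Of the translation initiation factors 9 then rose and 10 fell, and of the TCA and glyoxylate genes 6 rose and 8 fell. In footprints, 4 of 25 translation initiation factors rose and 17 fell, the poly(A)-binding protein gene PAB1 rising by 1.91 (SE 0.18). Of 75 mitochondrial ribosomal protein genes 21 rose and 37 fell, MRPS17 rising by 4.44 (SE 0.17). Of 22 genes of the TCA and glyoxylate cycles 2 rose and 16 fell, CIT2 having a log2 change of -2.23 (SE 0.17). Among 51 amino acid biosynthesis genes 6 rose and 34 fell, among 29 heat shock and chaperone genes 6 rose and 16 fell, and among 25 autophagy genes 8 rose and 14 fell, ATG40, a receptor of autophagy of the endoplasmic reticulum, rising by 3.42 (SE 0.17). Markers of dividing cells (20 measured) had 8 higher and 11 lower, CDC20, an activator of the anaphase-promoting complex, being 6.34 (SE 0.18) higher. Of 12 haploid-specific and mating genes 7 rose and 3 fell, STE18 by 6.94 (SE 0.27) and NEJ1 by 5.43 (SE 0.25) among those that rose. With a preset correlation that list was called (adjusted p = 8.5e-04), and the call was lost with an estimated correlation (adjusted p = 0.141). Of 5 mitochondrially encoded genes measured in mRNA none was called, and 3 were higher with rescaled libraries.

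**Figure D4:**
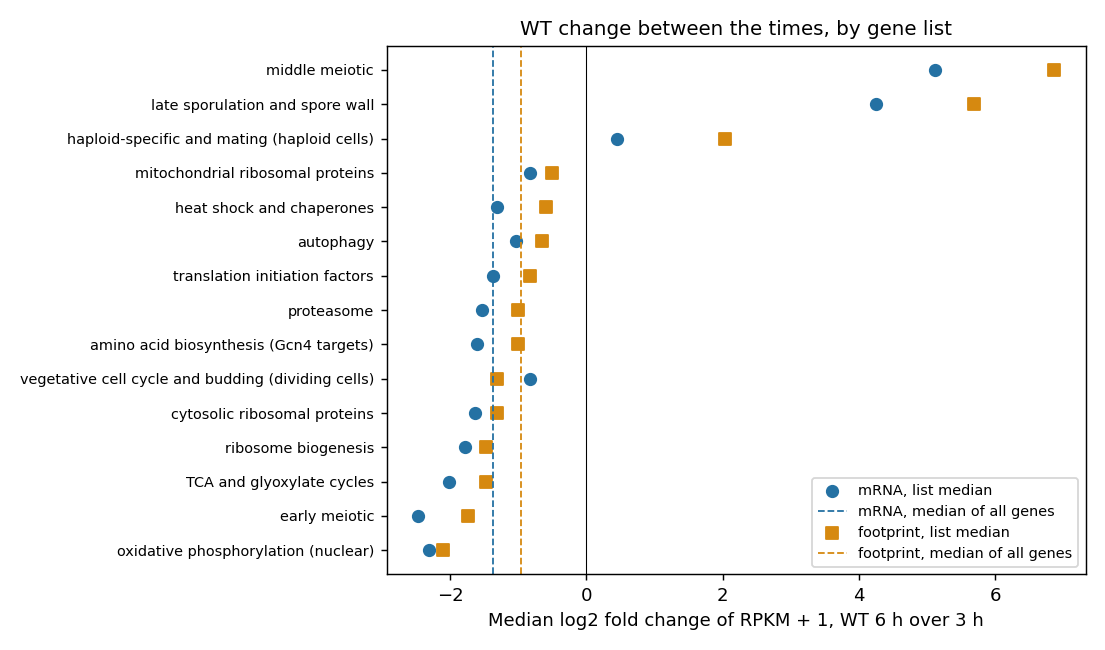
Median log2 fold change of RPKM + 1 between 3 h and 6 h in WT for each gene list, in mRNA (circles) and footprints (squares), with dashed lines at the median of all genes (-1.37 for mRNA, -0.96 for footprints). The middle meiotic list lies at 5.12 in mRNA and 6.86 in footprints.

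In WT mRNA, 596 genes rose and 3048 fell with all libraries. Without the library that did not match its label, which adds to the spread shared by the groups, 941 rose and 4158 fell. With the fixed replicate block 0 genes were called. The doubted library was kept in the fits without WT replicate 3 or 4. Those fits thus do not show whether the calls rest on a lone WT replicate. Without WT replicate 3 or 4, 0 genes were called (411 and 502 at an unadjusted p under 0.05). The median of all genes was -1.37, and with rescaled libraries 1486 rose and 1032 fell, or 2178 and 2061 without the library that did not match its label. SRD1 (6.59, SE 1.28), SPS4 (6.46, SE 1.50), SPR2 (6.43, SE 1.39), RRT12 (6.38, SE 1.29), GAT4 (6.38, SE 1.32) and the hexose transporter genes HXT10 (6.36, SE 1.40) and HXT14 (6.35, SE 1.32) were among the steepest rises, with YPR078C, YPR077C and YKR015C. The steepest falls included ADH2, an alcohol dehydrogenase gene (-3.82, SE 1.35), URA1 (-3.70, SE 1.32), FAA2 (-3.63, SE 0.81), JEN1 (-3.60, SE 0.99), ALD4 (-3.55, SE 0.81) and INO1, for inositol synthesis (-3.45, SE 0.88), with 4 short reading frames, YPR160W-A, YLR146W-A, YOL038C-A and YPL152W-A. Of 46 middle meiotic genes 44 rose and 1 fell (median 5.12), and of 38 early meiotic genes 35 fell (median -2.47; 37 adjusted over the list alone). Without that library 45 middle genes rose and 1 fell, and 38 early genes fell. The preset calls of both lists were lost (adjusted p = 0.393 and adjusted p = 0.895 with an estimated correlation). With rescaled libraries 45 of the middle genes rose and 22 of the early genes fell, or 45 and 30 without that library, when 1 early gene rose. DBP1 mRNA fell by 2.10 (SE 0.41) and MRP51 had 0.54 (SE 0.28, adjusted p = 0.113). With rescaled libraries DBP1 had -0.73 (adjusted p = 0.151), MRP51 rose by 1.92 (adjusted p = 0.0358), and ADH2, URA1 and YPR160W-A were not called.

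Translation efficiency in WT rose for 26 genes and fell for 15 between the times with all libraries, and rose for 1599 and fell for 131 without the library that did not match its label. The median log2 change of all genes was 0.50. With rescaled libraries it was 0.11, and with all libraries 18 genes then rose and 15 fell, 20 of the 41 calls being kept. Rescaled and without that library, 134 rose and 165 fell, and all 41 were kept. The 41 genes called with all libraries were all among the 1730. Taken as footprint minus mRNA per sample number, efficiency had 0 calls. The fits without a WT replicate kept the doubted library. Without deletion replicate 2 or 4, 2900 and 2891 genes were called, and without WT replicate 3 or 4 there were 0 (49 and 51 at an unadjusted p under 0.05). The largest rises were of TPO4 (4.78, SE 0.55), TPH3 (4.64, SE 0.50), MNE1 (4.61, SE 0.60), MES1, the methionyl-tRNA synthetase gene (4.33, SE 0.44), POP4 (4.17, SE 0.39), NDC80, a kinetochore gene known to be made as a poorly translated 5′-extended transcript early in meiosis (4.01, SE 0.28), HST1 (3.72, SE 0.38), ASM4 (3.55, SE 0.65), HAC1, the transcription factor of the unfolded protein response (3.36, SE 0.55), and ALR1 (3.27, SE 0.45). The largest falls were of YGR272C (-5.12, SE 0.78), YCR087C-A (-5.09, SE 0.76), EFG1 (-4.67, SE 0.74), MED7 (-4.58, SE 0.67), SOM1 (-3.24, SE 0.50), ORC1, of the origin recognition complex (-3.21, SE 0.45), GBP2 (-3.15, SE 0.35), SRP21 (-2.99, SE 0.46), UTP6 (-2.84, SE 0.42) and HAP4 (-2.81, SE 0.44). With all libraries, rescaled, 11 of the genes named here were not called, TPH3, HST1, ASM4, HAC1, ALR1, YGR272C, EFG1, MED7, ORC1, SRP21 and HAP4. The median efficiency change of 46 middle meiotic genes was 1.37, or 0.94 with rescaled libraries. With all libraries none of them was called, also adjusted over the list alone or rescaled, and the preset list test did not pass (adjusted p = 0.0890). Without that library 35 rose (38 adjusted over the list alone), but with rescaling 9 rose and 1 fell. The preset call of the list without that library (adjusted p = 2.7e-06) was lost with an estimated correlation (adjusted p = 0.985).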

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

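The tests of explanations, the values without the doubted mRNA library and the split counts without DBP1 were chosen after the results were seen, and the list tests and the other split counts were not. For 5 gene lists the effect of the deletion on mRNA differed between 6 h and 3 h by the interaction with a preset correlation: the median log2 difference was 1.14 for oxidative phosphorylation, 1.04 for early meiotic genes, -2.97 for middle meiotic genes, -2.44 for late sporulation and spore wall and -0.24 for haploid-specific and mating genes. The same 5 lists differed in translation efficiency, by -1.20, -1.06, 2.53, 2.81 and 0.40. The median of all genes was 0.61 in mRNA and -0.63 in efficiency, and with rescaled libraries the list medians were 0.51, 0.42, -3.57, -2.96 and -0.75 in mRNA and -0.56, -0.41, 3.15, 3.42 and 0.96 in efficiency. In footprints the middle meiotic list differed, by -0.34. None held with an estimated correlation (lowest adjusted p = 0.109). Without the mRNA library labelled deletion 3 h replicate 2 the mRNA medians, in the same order, were -0.04, 0.12, -0.98, -0.36 and -0.12, and those of efficiency 0.01, -0.14, 0.60, 0.66 and -0.01. Of these 5 lists only the middle meiotic and the late sporulation and spore wall lists were then called with a preset correlation, and neither with an estimated one (lowest adjusted p = 0.649).

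The mRNA library labelled deletion 3 h replicate 2 had a 6 h profile. A swap with a deletion mRNA library labelled 6 h would leave one of those near the WT 3 h profile, but the lower of them stood at 0.926. A culture that ran ahead would carry its footprints with it, but the footprint library of the same sample number stood at 0.0164, if that number marks 1 sample. What stays open is a wrong label or RNA of a 6 h deletion sample in that library, with which its position of 0.913 and its lack of DBP1 are consistent. Its recovered reads differed from those of deletion 6 h replicate 2 by 11.6 times the sampling variance, less than that replicate differed from deletion 6 h replicate 4 (24.3 times).

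Footprints in YPL119C-A appeared in the deletion libraries. A higher mRNA level alone does not account for them. At 3 h YPL119C-A mRNA was 203 and 169 RPKM in WT and 191 RPKM in the deletion library that matched its label. At 6 h it was 60.1 RPKM in WT and 160 RPKM in the deletion. Footprints were then 20.9-fold higher (95% exact binomial interval 6.85 to 104, counting error only). Without the doubted library the lower 95% limit of the efficiency change was at least 1.56 at both times. That limit depends on the pseudocount in WT and, at 3 h, on a lone deletion mRNA library. Footprints of DBP1 counted in its neighbour would be most frequent in WT, but the lowest deletion library held 29 reads and the highest WT library 2. A candidate explanation is that YPL119C-A is read on a DBP1 transcript that lost its own reading frame. Whether such a transcript kept its timing could not be decided. Without the doubted library, YPL119C-A mRNA changed between the times by 1.35 (SE 0.20) more on the log2 scale in the deletion than in WT. A lone deletion library then stood for 3 h. With all libraries the limma difference was 1.55 (SE 0.41, adjusted p = 0.651), which did not pass the threshold. A transcript with other timing, or a new junction made by the deletion, stays open too and was not tested.

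The deletion replicate 2 footprint libraries stood apart from the others of their time, with footprint correlations of 0.973 to 0.980 against 0.986 to 0.992 for pairs without them. After thinning to the shallowest library, pairs with replicate 2 correlated at 0.973 to 0.981 and pairs without it at 0.987 to 0.993. Thinning thus left the gap, and these values argue against a difference in depth as its cause. A shift along the line between the WT 3 h and 6 h profiles took 0.205% of the squared difference between replicates 2 and 4 in footprints at 3 h. At 6 h it took 11.4% in footprints and 16.4% in mRNA. Between the WT replicates it took 0.0568% and 0.261% in footprints at 3 h and 6 h, and 16.2% and 0.272% in mRNA. At 6 h replicate 2 stood at 0.942 in footprints and 0.926 in mRNA, and replicate 4 at 1.04 and 1.03. A lag in stage thus stays open for a small part of the difference at 6 h. A difference of culture or handling in that replicate stays open, and no biological explanation was tested, since replicate 4 carries the same deletion.

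For the average over the times, 34 splits of the 8 combinations of strain, time and replicate were compared. In mRNA 1 of them, the real one, gave as many genes (1 gene, highest other 0), but that gene was DBP1, whose removal defines the groups, so this count says nothing about chance. In footprints 2 of 34 splits gave as many genes (2 genes, highest other 6), or 3 of 34 without DBP1 (1 gene), and in translation efficiency 2 of 34 did (1 gene, highest other 1), so for these counts chance cannot be excluded. The footprint split with 6 genes put WT 3 h replicate 3 with the deletion libraries other than 6 h replicate 4.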

How the results depend on the processing

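No named gene reversed a called direction under any alternative run; over all alternatives 176 values of 53 single-gene results lost a call and 45 values of 26 gained one. limma without the trend called 1 gene in mRNA at 6 h. A pseudocount of 5 RPKM called 1 gene in translation efficiency at 6 h and 2 averaged over the times. Median-ratio rescaling called 1 gene in the footprint difference between the times. It kept 2919 and reversed 144 of the 4430 calls between the times in WT footprints, as it moves the median of all genes from -0.96 to -0.02. limma-voom called 1 gene in footprints at 6 h, DBP1. Without the mRNA library labelled deletion 3 h replicate 2, 2 genes were called in mRNA at 6 h, and in translation efficiency 1 at 6 h (the deleted DBP1), 2 averaged over the times and 1730 between the times in WT. With rescaling as well these counts were 2, 1, 2 and 299. The cause of these changes was not tested, except that the count of 1730 follows a narrower median 95% interval of efficiency changes, from ± 1.23 to ± 0.55.

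The numbers were not taken to pair libraries, as the labels do not say so. In the sample titles the strains have replicate number 4 alone in common, but the column headers give both strains the same replicate numbers. Leaving out those with the doubted library, differences between replicates correlated across genes from -0.04 to 0.24 between the times and between footprints and mRNA from -0.34 in WT at 3 h to 0.67 in the deletion at 6 h, so a pairing of some libraries stays open. With the replicate block as footprint minus mRNA per sample number, 0 genes were called in translation efficiency at 3 h, averaged over the times and between the times in WT. With the fixed replicate block, 0 were called in WT mRNA between the times. It moved no other count by over 1.5 times.

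Leaving out each replicate in turn gave 0 to 5069 genes in mRNA at 3 h, 0 to 53 at 6 h, 0 to 4641 averaged, 0 to 4866 for the difference between the times and 0 to 5243 between the times in WT. Footprints gave 2 to 77 at 3 h, 1 to 11 at 6 h, 2 to 123 averaged and 0 to 1 for the difference. Translation efficiency gave 0 to 4436 at 3 h, 0 to 1 at 6 h, 0 to 3807 averaged, 0 to 4036 for the difference and 0 to 2900 between the times in WT. A lone library was taken to vary like the other groups. Apart from the footprint difference between the times, the highest counts between the strains came without deletion replicate 4, which in mRNA leaves the doubted library alone in its group. Genes at 4 to 6 RPKM had a median of 36.1 reads per mRNA library and 40.9 per footprint library. Short genes can pass the filter on far fewer, as YBL039C-A did with at most 3 reads in any footprint library.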

Other observations

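The tests here were chosen after the data were seen. In the deletion replicate 2 libraries, ribosome biogenesis genes were above WT by a median log2 difference of 0.29 in footprints at 3 h and 0.53 at 6 h, and in replicate 4 by 0.24 and -0.12. At 6 h early meiotic genes were at 0.39 in replicate 2 and -0.22 in replicate 4, and proteasome genes at 0.23 and -0.22. Cytosolic ribosomal protein genes were at -0.26 in replicate 2 and 0.41 in replicate 4 at 3 h. Of these medians, only that of ribosome biogenesis at 3 h had 1 sign in both replicates. In mRNA at 6 h ribosome biogenesis genes were at 0.50 in replicate 2 and -0.02 in replicate 4. Early meiotic genes were there at 0.40 and -0.21, and proteasome genes at 0.24 and -0.25. The opposite signs of these lists at 6 h were thus not confined to footprints. Other lists had 1 sign at 3 h in footprints. Middle meiotic genes were at 0.35 in replicate 2 and 0.23 in replicate 4, and late sporulation and spore wall genes at 0.31 and 0.23. In the replicate 4 mRNA library labelled 3 h these lists were at 0.87 and 0.72. At 6 h the signs in footprints differed, with -0.23 and 0.03 for the middle meiotic list and -0.11 and 0.07 for the late list.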
